A study of Bos taurus with 2 samples.

How the data were processed

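Single-cell RNA profiles were measured in bovine embryos recovered by flushing at day 25 that carried bovine embryonic stem cells, so each embryo was a chimera of host and donor-derived cells. Per the labels' protocols, the embryos were minced, digested with papain and DNase, strained and sorted before loading on a 10x Genomics 3' v3.1 droplet system; the gate of the sort is not given in the sources used here. The 2 samples carry 1 label and are replicates 1 and 2 of 1 group, so no groups of samples were compared, and every comparison is between cell classes within the same 2 suspensions. Nothing in the labels says that the 2 samples came from separate embryos. The p-values therefore rest on the spread between these samples only, for most genes mainly as pooled over genes. That spread may be technical. The labels do not say which cells carried a GFP transgene or how many donor-derived cells the embryos held.

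The deposited values are raw UMI counts per gene and cell, with no normalization by the authors; UMIs are molecular tags that count each captured RNA molecule once. Per the submitters' processing notes, reads were processed with Cell Ranger against the bosTau9 genome build, and R 4.1.2 and Seurat 4.3.0 were used; the Cell Ranger version and the annotation are not given in the sources used here. In the deposited counts every cell had between 201 and 3999 detected genes and at most 4.98% mitochondrial counts, so cells had been filtered before deposit, and cells with many detected genes are not analysed here. Each column was matched to its sample by the sample number in its name. The table holds 17846 gene symbols, among them a GFP row, and 499 of them had no count; 17337 symbols were found in a RefSeq gene table of another assembly, ARS-UCD2.0, which was used for names only. Gene symbols are printed as the authors' table gives them. Near-identical family members (pregnancy-associated glycoproteins, prolactin-related proteins, globins, histones) and genes with processed copies (KRT8, KRT18, FABP5) are uncertain where counting could split their reads.

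Replicate 1 held 1973 cells and 11182089 UMIs (median 4889 per cell) and replicate 2 held 2464 cells and 15427708 UMIs (median 5601 per cell). The 2 libraries were not the same library deposited more than once: a chi-square test of their gene totals gave 14.7 per degree of freedom over 15260 genes, and 6 barcodes occurred in both. Cells with 500 or more detected genes and under 20% mitochondrial counts were kept. Scrublet, run per sample with an assumed doublet rate of 0.06, called 3 doublets, which were removed; with so few calls, doublets were hardly assessed. The 4356 kept cells (1939 and 2417) were scaled to 10000 counts, log-transformed and reduced to 2000 variable genes, 30 principal components and 15 neighbours, then clustered by the Leiden method at resolution 1 (scanpy 1.11.5, igraph 0.11.9, Python 3.11.15). Genes of 22 lists, mitochondrial genes, ribosomal protein genes and GFP took no part in the clustering, so that a class could be compared on genes that did not define it; genes correlated with the lists did take part.

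Clusters were named from 23 marker lists fixed before the data were examined. A marker counted when it was in at least 25% of a cluster's cells at 2-fold or more over the mean of the other clusters (pseudocount 20 CPM, the UMI counts of a sum scaled to a fixed library total); a name needed 3 such markers, 1 of them among the 200 leading genes, and more markers than any other name. A cluster stayed unnamed when over 90% of its cells came from 1 replicate, or when its 10 leading genes held more markers of another class or went against the name. A cluster with no name but with markers of several classes in 5% of its cells was clustered again. Only the markers were fixed beforehand. An earlier rule (markers in 10% of cells, 1 of them among the 50 leading genes) was replaced after its class sizes had been seen and before any test, and the counts it gives are among the added alternatives. In the class contrasts it was run together with a minimum of 10 cells, since it left 10 mesenchyme-like cells in replicate 1, and the same 3 classes were set against each other. Clusters of 1 name were summed per replicate into 1 class, and the rest are called by number.

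Classes with 20 or more cells in each replicate (neuron-like, neural progenitor-like and mesenchyme-like) entered 1 fit of summed raw counts with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr, the quasi-likelihood test with robust estimation, replicate as a block, and Benjamini-Hochberg adjustment over all genes tested at 0.05. Replicates pair the sums by design, since the classes of 1 number come from 1 suspension. Each gene had 2 residual degrees of freedom, against a median of 62.2 lent by the spread pooled over genes. Each class was set against the equal-weight mean, on the log scale, of the other 2 classes, so a gene at a middle level may be higher than that mean and lower than in 1 of the classes; each pair of classes was therefore also tested on its own, an alternative added after the data were seen. The planned contrast of extraembryonic with embryonic classes could not be run with 20 cells, because no extraembryonic class reached that number. It was run with a minimum of 10 cells per replicate, as an addition, between the trophoblast-like class and the mean of both neural classes. That fit had 3 residual degrees of freedom, and the median number lent by pooling was infinite. Its very small p-values therefore rest on the pooled spread, not on each gene's own. Only genes of the 22 lists are reported: 533 of the 554 genes written were in the table. These were lists of pluripotency, DNA methylation enzyme, imprinted, interferon response, basement membrane and matrix, glycolysis, cholesterol synthesis, steroid synthesis, nutrient transport, WNT, BMP and TGF-beta, FGF, Notch, hedgehog, anterior, trunk and posterior HOX, epithelial junction, mesenchymal, cell cycle, dissociation stress and hypoxia genes. Each list was tested against the other genes with camera (limma 3.58.1), with a preset correlation of 0.01 and with an estimated one, adjusted over lists and contrasts.

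Named genes followed a rule fixed before the data were examined: list genes past the threshold, with 1 sign in both replicates and at least 50 CPM on the higher side, taken as the 12 highest and 8 lowest fold changes of each class, the 15 highest and 10 lowest of the trophoblast contrast, and further members of a list. The rule allows up to 4 further members of every list; at most 2, and only of lists called with the preset correlation, are named. That narrowing was made after the alternatives had been seen, and totals over all genes of the rule are given in the closing section. POU5F1, NANOG and SOX2 are given whatever their values, and genes of numbered clusters were chosen after the data were seen. Some genes that the rule names are not reported here. Levels are CPM of the summed UMIs, mean ± SD over the 2 replicates. A fold change without 1 replicate is the same contrast fitted to the other replicate alone, with the offsets, dispersions and prior count of the fit to both. It replaced, after its values had been seen, a difference of log2 CPM with a prior count of 2, which drew low genes toward 0 and so mixed a change of method with the loss of a replicate. That difference is still what the sign in each replicate was read from. Where a side had no count, the fold is a bound against a floor of 3 counts over both replicates; with 1 to 3 counts it is a ratio with an exact 95% interval. Both are set against the pooled UMIs of the other classes, not their equal-weight mean. These intervals and floors, and the Poisson and Clopper-Pearson intervals, cover counting error only.

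The fits were tested on simulated counts drawn from each gene's mean over all sums and the real library sizes. All classes shared these means, apart from a small set of genes changed equally up and down and a list of doubled genes. The real classes differed in far more genes, so these rates need not hold for the real contrasts. In a simulation of the neuron contrast over 11024 genes, 13 of 47 genes changed 1.5-fold, 33 of 48 changed 2-fold, 43 of 48 changed 4-fold and 47 of 47 changed 8-fold were recovered, and 1.22% of the calls were unchanged genes. In one of the trophoblast contrast over 10475 genes the numbers were 0 of 46, 9 of 42, 22 of 49 and 29 of 44, with 7.04% of the calls unchanged genes. A simulated list of doubled genes had an unadjusted camera p of 9.99e-57 (neuron) and 1.03e-21 (trophoblast) with the preset correlation. With an estimated correlation camera gave it 0.00927 and 0.00169. Once adjusted over many lists, a p of 0.00927 may not pass, so that setting can miss a list that moved. Each simulation drew genes independently and held 1 doubled list, so the power of that setting was not measured. Alternatives fixed beforehand were DESeq2's size factors in edgeR, DESeq2 1.42.0 itself, no filter on low counts, no replicate block, doublets kept, Leiden resolution 0.5, a minimum of 1000 genes per cell, Leiden resolution 2 and scaling within each sample for the class shares alone, and leaving out each replicate, which leaves no residual degrees of freedom and so no test. Added after the data were seen were the earlier naming rule, the 10-cell minimum in the class fit, cells with a ribosomal protein share of 10% or more, the pairs of classes, GFP by class, the share of a named gene's UMIs in each cluster of its class, and a fit that also held the numbered clusters with 20 or more cells per replicate. The 2 libraries themselves were compared with no test, by a rule of size: 2-fold or more in 1 direction in every class tested and 50 CPM or more over all cells of 1 replicate. Earlier tests of GFP in cells thinned to fixed UMIs and in cells with 10% or more ribosomal protein counts, and of bare nuclei by the mitochondrial share, could not decide their explanations and were replaced after their values had been seen.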

Results

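Cells of day 25 bovine chimeric embryos were profiled in 2 replicates of 1 group. The question named by the series is how bovine embryonic stem cells take part in embryonic and extraembryonic differentiation. The 4437 deposited cells had a median of 5247 UMIs and 2696 detected genes per cell. Cell classes were compared within each replicate, and all shares are shares of sorted cells. Levels are CPM, given as mean ± SD of the 2 replicates, and fold changes are edgeR's log2 values with their standard error (SE) and adjusted p.

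Among the 4356 kept cells 30 clusters were found, and 5 classes were named from their markers. Neural progenitor-like cells, with the neural transcription factors SOX2, PAX6 and SOX1 and the Notch target HES5, made up 16.1% ± 0.0560 (SD, n = 2; 312 and 387 cells in replicates 1 and 2). Neuron-like cells, with the cytoskeletal genes DCX and STMN2 and the RNA-binding ELAVL4, made up 10.7% ± 0.454 (213 and 250 cells). Mesenchyme-like cells, with the fibrillar collagen genes COL1A1 and COL3A1 and the proteoglycan DCN, made up 3.15% ± 0.875 (49 and 91 cells). Trophoblast-like cells, with pregnancy-associated glycoproteins and prolactin-related proteins, made up 0.702% ± 0.174 (16 and 14 cells). Erythroid-like cells, with embryonic globins, made up 0.687% ± 0.315 (9 and 22 cells). The remaining 68.7% ± 0.507 of cells stayed unnamed.

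Some classes were built from unlike clusters. Of the mesenchyme-like clusters, cluster 15 was also led by the plasma protein genes APOA1 and RBP4, and cluster 20.2 was led by POSTN, DCN and IGF2. Of the trophoblast-like clusters, cluster 20.0 was led by PAG2 and PAG8 and cluster 25 by PRP1 and PRP4. Of the neuron-like clusters, cluster 5 (325 of 463 cells) was led by NRXN3 and LRRTM4, and cluster 14 (112 cells) by DCC and EYA2, with DLL3 and HES6 among its 10 leading genes. RSPO2 led cluster 21, with 98 of the 699 neural progenitor-like cells. GATA3, a transcription factor of trophoblast, stood at 252 CPM in trophoblast-like and 354 CPM in all other cells, and PAG1 had no count in trophoblast-like cells. Of the mesenchyme markers, OGN stood at 1.07 CPM in mesenchyme-like and 10.3 CPM in all other cells, and TWIST2 at 3.21 and 4.77 CPM. The other markers of that list were higher in mesenchyme-like cells.

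In this clustering no cluster was named for yolk sac or hepatic endoderm, gut endoderm, neural crest, surface ectoderm, amnion ectoderm, somitic, presomitic, intermediate or lateral plate mesoderm, notochord or cardiomyocyte. Nor was one named for endothelium, myeloid, megakaryocyte, smooth muscle, mesothelium, primordial germ cell or maternal endometrial epithelium. The earlier naming rule gave names to gut endoderm (17 and 12 cells in replicates 1 and 2) and somitic mesoderm (8 and 11), and keeping doublets gave one to surface ectoderm (1 and 6). Clusters 7, 16 and 20.4 were kept out of a class because their leading genes held more markers of another. They held 3.87% and 3.60%, 0.928% and 1.37%, and 0.413% and 0.455% of cells in replicates 1 and 2. Cluster 23, almost all from replicate 2, held 0.0516% and 2.85%, and cluster 24, whose leading genes went against its name, 0.877% and 0.496%. The share of neural progenitor-like cells depended on the clustering, with 1.48% at Leiden resolution 2 and 18.4% at resolution 0.5.

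Ribosomal protein genes took a small part of the counts in most cells. The median share per cell was 2.88% ± 1.10 in neuron-like, 5.01% ± 0.231 in neural progenitor-like, 24.5% ± 0.227 in mesenchyme-like and 26.8% ± 5.40 in trophoblast-like cells (SD, n = 2). This share therefore moved with every contrast of those classes. The median mitochondrial share was 0.217% ± 0.0171, 0.249% ± 0.0446, 1.06% ± 0.158 and 0.309% ± 0.234 in the same order. The ribosomal protein share was under 10% in 68.3% of the cells of replicate 1 and 59.7% of those of replicate 2. The counts of each class contrast were also taken in cells with a ribosomal protein share of 10% or more.

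The 2 replicates were compared in the 3 classes of 20 or more cells. Across genes of 50 CPM or more, which are not independent replicates of each other, Pearson's r of the log2 levels was 0.953 in neuron-like, 0.978 in neural progenitor-like and 0.960 in mesenchyme-like cells. By the rule of size, 3 genes differed, and LRRTM4 was no longer among them with TMM-scaled CPM or with classes thinned to equal totals, which left 2. PRP4, a prolactin-related gene of the trophoblast (74.4 and 10.7 CPM over all cells of replicates 1 and 2), and LRRTM4, a synaptic adhesion gene (61.2 and 29.1 CPM), were lower in replicate 2. AHSG, which encodes the plasma protein fetuin-A (0.358 and 59.0 CPM), was higher. Trophoblast-like cells were not compared in this way, and among their markers TKDP4 stood at 412 and 2801 CPM and PRP1 at 6202 and 2308. With 1 sample on each side these differences have no replicate check.

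SOX2 was abundant and POU5F1 and NANOG were nearly absent. SOX2, which also marks neural progenitors and was among the naming markers, reached 386 and 435 CPM in neural progenitor-like cells of replicates 1 and 2. It stood at 116 and 116 in neuron-like, 19.3 and 5.48 in mesenchyme-like, 5.56 and 0 in trophoblast-like and 0 and 5.53 in erythroid-like cells. It was not confined to the progenitor-like class, since unnamed clusters held similar levels, with 359 and 356 CPM in cluster 1, 358 and 320.0 in cluster 4, 342 and 332 in cluster 0 and 326 and 348 in cluster 16. POU5F1 had 2 UMIs in each replicate over all kept cells, of which 1 lay in a mesenchyme-like cell of replicate 1 and none in the other named classes. Finding 0 of 312 and 0 of 387 neural progenitor-like cells with a POU5F1 UMI allows a share of up to 0.962% and 0.775%. In trophoblast-like cells the limits were 18.8% and 21.4%. NANOG had 1 UMI, in an unnamed cell of replicate 2. These limits hold for cells with a UMI, not for cells that express the gene.

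**Figure D1:**
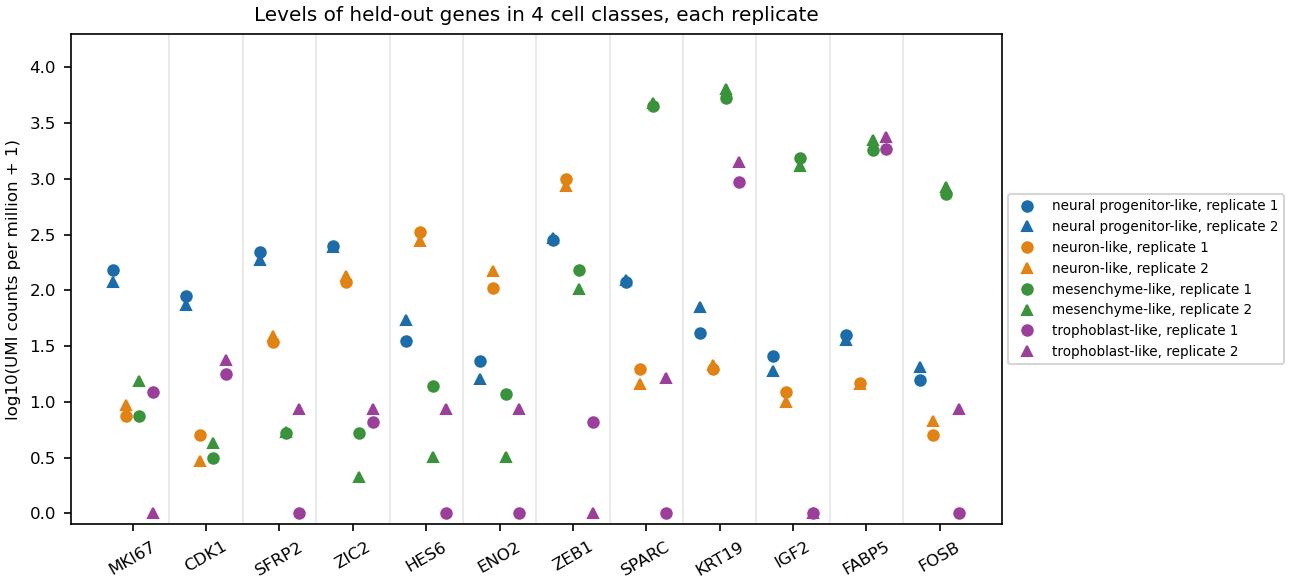
Levels of 12 genes held out of the clustering in 4 cell classes, on a log10(CPM + 1) scale, where each point is 1 replicate of 1 class (circles replicate 1, triangles replicate 2) and a point at 0 had no count. MKI67 stood at 134 CPM in neural progenitor-like and 7.39 in neuron-like cells, and SPARC at 4629.9 in mesenchyme-like cells.

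Neural progenitor-like cells had high levels of MKI67, RSPO2, SFRP2 and HHIP. MKI67, a marker of dividing cells, stood at 134 CPM ± 22.2 against 7.39 ± 1.33 in neuron-like and 10.3 ± 5.54 in mesenchyme-like cells. Its log2 fold change against the mean of both was 3.31 (SE 0.23, adjusted p = 3.42e-19). RSPO2, a secreted amplifier of WNT signalling, stood at 120 CPM ± 30.7 (log2 4.71, SE 0.33, adjusted p = 6.72e-15), and 96.6% of its UMIs in the class lay in cluster 21, which held 22.1% of the UMIs of the class. SFRP2, a secreted WNT modulator, stood at 202 ± 21.8 (log2 3.49, SE 0.22, adjusted p = 7.38e-21), and HHIP, a decoy receptor for hedgehog ligands, at 184 ± 42.8 (log2 3.39, SE 0.22, adjusted p = 3.47e-20). MKI67 had 4.05 without replicate 2 and RSPO2 5.84 without replicate 1.

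The R-spondin receptor LGR5 (log2 3.46), the zinc finger factors ZIC2 (3.38) and ZIC5 (3.02), and the division genes CDK1 (4.24), CDC6 (3.60), KIF11 (3.36), MCM3 (3.22) and CENPF (2.95) were also among the highest. Among the lowest were the matrix genes COL5A1 (log2 -3.60), LAMA5 (-3.58), TNC (-3.39) and LAMB1 (-3.30). The tropomyosin TPM2 (-3.42), the matrix-bound TGFBI (-3.34) and the transcription factor KLF2 (-3.34) were as low. COL6A1, a type VI collagen gene, had 2 UMIs in the class and 734 in the others pooled, a 375-fold lower level (95% counting interval 103 to 3103), but 733 of these lay in mesenchyme-like cells and 1 in neuron-like cells, and progenitors and neurons did not pass against each other (adjusted p = 0.946). Against neuron-like cells alone, RSPO2, CENPF and SFRP2 were also higher in progenitors (log2 of neuron over progenitor -5.83, -3.42 and -2.29; adjusted p = 7.25e-15, 8.44e-05 and 3.81e-16). Without replicate 1, RSPO2 had 5.84, CDC6 4.29, CENPF 2.33 and KLF2 -0.74. Without replicate 2, LGR5 had 5.01, CENPF 3.76, TPM2 -4.20, TNC -1.53 and KLF2 -5.31, and COL6A1 was 233-fold lower.

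Of the 374 list genes tested, 140 were higher and 97 lower in neural progenitor-like cells, and 137 did not pass. Of the cell cycle genes, 34 of 35 were higher and none lower, with RRM2, a subunit of the enzyme that makes DNA precursors (log2 2.67), and the cyclin CCNB2 (2.66) among them. Without replicate 2, RRM2 had 3.39 and CCNB2 5.74. Set against all other genes, this list was called with the preset correlation (adjusted p = 2.39e-15) and not with an estimated correlation (adjusted p = 0.581). Correlated genes took part in the clustering, and CDCA2, KIF18B and ASPM, genes of mitosis, led cluster 9 with 251 of the progenitor-like cells. This cluster held 33.7% of the UMIs of the class, but 88.8% of those of CDK1, 87.7% of those of KIF11 and 63.2% of those of MKI67. WNT genes rose in 14 and fell in 2 of 30 (ZNRF3, a ligase that removes WNT receptors, log2 1.29; FZD3, a WNT receptor, 1.40). Hedgehog genes rose in 6 of 11 with none lower (SMO, the signal transducer of the pathway, 1.34, and the co-receptor BOC, 1.08). Nutrient transport genes rose in 14 and fell in 1 of 23 (the arginine transporter SLC7A2, 2.15, and the fatty acid binding FABP5, -2.66). These 3 lists had adjusted p = 0.0101, 0.0119 and 0.00531 with the preset correlation and adjusted p = 0.581 each with an estimated correlation. Matrix genes fell in 23 and rose in 2 of 32 (FBLN1 -3.07, COL6A2 -2.29). Dissociation stress genes fell in 11 of 21 with none higher (the early response genes JUNB -2.65 and DUSP1 -2.56). Imprinted genes fell in 15 and rose in 3 of 20 (the growth factor IGF2 -3.00, the zinc finger gene PLAGL1 2.71). For these lists the preset correlation gave adjusted p = 3.48e-06, 9.24e-06 and 2.39e-05, and an estimated correlation adjusted p = 0.581 each. The falls in matrix and dissociation stress genes were mostly falls against mesenchyme-like cells. Against these alone, 29 of 32 matrix genes were lower in progenitors and 1 higher, and 20 of 21 stress genes were lower and 0 higher. Neuron-like cells lay below progenitors in 19 matrix and 14 stress genes, and above them in 3 of each.

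Among signalling lists that were not called in neural progenitor-like cells, BMP and TGF-beta had 14 higher and 6 lower of 29 genes, FGF 7 and 3 of 16, and Notch 10 and 2 of 16. Metabolic lists not called were glycolysis (5 higher, 2 lower of 23), cholesterol synthesis (4, 7 of 22), steroid synthesis (1, 2 of 5) and hypoxia (6, 3 of 14). The others were pluripotency (5, 3 of 12), DNA methylation enzymes (5, 2 of 12), interferon response (2, 1 of 9), anterior HOX (0, 2 of 8), trunk HOX (0, 1 of 7), epithelial junction (5, 4 of 13) and mesenchymal (3, 7 of 16). Adjusted over the list alone the counts were the same except for matrix (3 higher), steroid synthesis (3 lower) and epithelial junction (5 lower). The sign of the median, mean or test differed for glycolysis, hypoxia and interferon response.

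Of the 140 genes higher in progenitors, 122 were also higher than in neuron-like and 98 than in mesenchyme-like cells alone, with 2 and 9 in the opposite direction. Of the 97 lower, 31 were also lower than in neuron-like cells and 27 higher, and 87 were lower than in mesenchyme-like cells. In cells with 10% or more ribosomal protein counts 185 genes were called, 161 of them shared in direction, and KLF2 (log2 -1.07) and COL6A2 (-1.20) lost their calls. With DESeq2, KLF2 (-3.71) and CCNB2 (3.09) were not called, nor was KLF2 (-3.31) without the replicate block. With Leiden resolution 0.5, BOC (0.06) and IGF2 (-0.57) were not called. With the earlier naming rule and the 10-cell minimum together 71 genes were called.

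Neuron-like cells had high levels of DLL3 and HES6 and low levels of SPARC and KRT8. DLL3, a Notch ligand that acts within the cell, stood at 184 CPM ± 19.4 against 10.3 ± 9.83 in neural progenitor-like cells and no count in mesenchyme-like cells (log2 7.72, SE 0.45, adjusted p = 8.14e-13). Since 1 of the classes compared had no count, the size of this log2 value depends on the fit's prior count. HES6, a HES family gene that favours neuronal differentiation, stood at 304 ± 43.5 against 43.4 ± 13 in neural progenitor-like and 7.53 ± 7.54 in mesenchyme-like cells (log2 4.03, SE 0.22, adjusted p = 1.93e-19). Cluster 14, with 24.6% of the UMIs of the class, held 85.4% of those of DLL3 and 72.2% of those of HES6. ENO2, the neuronal enolase, stood at 126 ± 32.7 (log2 3.52, SE 0.26, adjusted p = 6.07e-16). ZEB1, a zinc finger repressor (log2 2.11), the neural cadherin CDH2 (1.74), the imprinted GTPase gene DIRAS3 (2.37) and the MYC antagonist MXI1 (2.27) were also higher. So were the hindbrain gene HOXB2 (1.88), FZD3 (1.95), FGF12 (2.00) and the fibrillin FBN1 (1.92). ZIC2 (log2 2.22) lay above the mean of the other classes but below neural progenitor-like cells, at 125 CPM ± 10.6 against 247 ± 1.57 (log2 -0.77, SE 0.17, adjusted p = 8.15e-05). Without replicate 1, ENO2 had 4.49 and MXI1 2.86, and without replicate 2 ENO2 had 2.55.

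Among the lowest in neuron-like cells were SPARC, a matrix glycoprotein (log2 -5.75, SE 0.26, adjusted p = 4.25e-29), and the epithelial keratin KRT8 (-6.13, SE 0.30, adjusted p = 1.21e-22). The collagen COL12A1 (-5.77) and the glutamate transporter SLC1A3 (-5.64) were also low. COL6A3 had no UMI in the class, a level at least 101-fold lower than in the others pooled, of whose UMIs 607 were mesenchyme-like and 3 progenitor-like. WNT2B, a WNT ligand, was 43.1-fold lower (95% counting interval 14.6 to 211), TGFBR3, a TGF-beta co-receptor, 45.1-fold (12.3 to 375), and COL6A1, with 1 UMI, 365-fold (65.2 to 14416). For COL6A1 and COL6A3 this rests on mesenchyme-like cells, since neither passed against progenitors alone (adjusted p = 0.946 and 0.182), whereas WNT2B and TGFBR3 did (log2 -4.39 and -3.57). Without replicate 1, COL12A1 had -6.88 and SLC1A3 -4.94, and WNT2B was 72.5-fold, COL6A1 234-fold, TGFBR3 at least 19.9-fold and COL6A3 at least 62.4-fold lower. Without replicate 2, COL12A1 had -5.00 and SLC1A3 -7.41, and WNT2B was 28.4-fold, TGFBR3 14.4-fold, COL6A1 at least 41.2-fold and COL6A3 at least 37.2-fold lower.

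Of the 374 list genes, 57 were higher and 205 lower in neuron-like cells, and 112 did not pass. Cell cycle genes fell in 30 of 35 with none higher (the helicase HELLS -2.66, MKI67 -2.58). Matrix genes fell in 29 and rose in 1 of 32 (COL18A1 -5.14, NID1 -4.92), and dissociation stress genes fell in 20 of 21 with none higher (FOSB -4.73, IER3 -4.44). These 3 lists had adjusted p = 2.59e-08, 7.38e-13 and 4.50e-10 with the preset correlation and adjusted p = 0.581 each with an estimated correlation. BMP and TGF-beta genes fell in 19 and rose in 5 of 29 (FST, a secreted activin inhibitor, -3.91, BMP7 -3.84), and epithelial junction genes fell in 9 and rose in 1 of 13 (the keratins KRT19 -5.06 and KRT18 -4.76). Mesenchymal genes fell in 12 and rose in 3 of 16 (the collagen crosslinking enzyme LOX -5.19, SNAI2 -4.15), and nutrient transport genes fell in 14 and rose in 3 of 23 (FABP5 -4.51, the glutamine transporter SLC1A5 -3.50). For these lists the preset correlation gave adjusted p = 7.22e-05, 0.000327, 0.000639 and 0.0119, and an estimated correlation adjusted p = 0.581 each. Without replicate 1, NID1 had -6.22, IER3 -5.05 and BMP7 -4.75. Without replicate 2, NID1 had -4.15, IER3 -3.73, BMP7 -3.03, KRT18 -4.13 and SNAI2 -4.99.

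Among lists not called in neuron-like cells, imprinted genes were higher in 9 and lower in 6 of 20, WNT genes in 5 and 14 of 30, and Notch genes in 3 and 5 of 16. FGF (4 higher, 6 lower of 16), hedgehog (1, 5 of 11), anterior HOX (3, 1 of 8), trunk HOX (0, 2 of 7), pluripotency (3, 5 of 12) and DNA methylation enzymes (5, 5 of 12) were not called either. The rest were interferon response (0, 3 of 9), glycolysis (5, 7 of 23), cholesterol synthesis (2, 6 of 22), steroid synthesis (2, 0 of 5) and hypoxia (2, 7 of 14). Adjusted over the list alone the counts were the same except for imprinted (7 lower), cholesterol synthesis (5 lower), WNT (6 higher) and trunk HOX (1 lower). Median, mean and test did not share a sign for glycolysis and anterior HOX.

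Neuron-like and neural progenitor-like cells differed in 257 of the 374 genes, of which 56 were higher in neuron-like cells. Lower in neuron-like cells were 34 of 35 cell cycle, 20 of 30 WNT, 20 of 29 BMP and TGF-beta, 10 of 16 Notch, 8 of 11 hedgehog and 19 of 32 matrix genes. Of the imprinted genes 12 of 20 were higher and 3 lower. Of the 57 genes higher against the mean of both classes, 43 were also higher than in progenitors alone and 4 lower, and of the 205 lower, 157 were also lower and 4 higher. In cells with 10% or more ribosomal protein counts 224 genes were called against the mean of both classes, 206 of them shared in direction, and FGF12 (log2 0.62) and FBN1 (0.08) lost their calls. With a minimum of 1000 genes per cell KRT8 (-4.19) and COL6A1 lost theirs and FBN1 turned to -0.05. With the earlier naming rule and the 10-cell minimum together 147 genes were called.

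Mesenchyme-like cells had high levels of SPARC, KRT19, IGF2 and FABP5. Most cells of the class (114 of 140) lay in cluster 15, which was also led by APOA1 and RBP4. The levels are those of the class as a whole and are not set out by cluster here. SPARC reached 4629.9 CPM ± 191 against 67.8 ± 0.0883 in the mean of both neural classes (log2 7.42, SE 0.20, adjusted p = 6.90e-43). KRT19, an epithelial keratin, reached 5854 ± 823 against 37.3 ± 11.1 (8.18, SE 0.20, adjusted p = 2.53e-44), and IGF2, a fetal growth factor, 1422 ± 168 against 15.8 ± 3.16 (7.28, SE 0.19, adjusted p = 5.99e-43). FABP5 reached 2001 ± 289 against 25.2 ± 1.42 (7.17, SE 0.19, adjusted p = 1.64e-42).

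TNC (log2 7.69), COL12A1 (7.45), TPM2 (7.38), KLF2 (7.33) and the early response gene FOSB (7.09) were also among the highest in mesenchyme-like cells. For 3 genes with few UMIs in the neural classes the level was 1039-fold (COL6A3, 95% counting interval 354 to 5050), 1254-fold (COL6A1, 427 to 6095) and 364-fold higher (HEPH, an iron exit oxidase, 99 to 3038). Among the lowest, DLL3 had no UMI, at least 36.9-fold lower than in the neural classes. ZIC2 was 91.4-fold (31.2 to 444) and ZIC5 49.8-fold lower (13.7 to 412), and HES6 (log2 -3.60), SFRP2 (-3.56), HHIP (-3.38), FZD3 (-3.35) and CDH2 (-3.10) were lower as well. Without replicate 1, COL12A1 had 8.10, KLF2 9.61 and HES6 -5.03, and ZIC2 was 184-fold lower. Without replicate 2, TNC had 9.52, TPM2 8.22 and HES6 -2.40, HEPH was 194-fold higher, ZIC2 45.4-fold lower and DLL3 at least 11.2-fold lower.

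Of the 374 list genes, 170 were higher and 84 lower in mesenchyme-like cells, and 120 did not pass. Matrix genes rose in 29 and fell in 2 of 32 (COL6A2 7.01, COL5A1 6.86), and dissociation stress genes rose in 20 of 21 with none lower (IER3 5.02, JUNB 4.99), in the class with the higher mitochondrial share (1.06%). Mesenchymal genes rose in 13 and fell in 3 of 16 (LOX 5.83, SNAI2 5.73), and epithelial junction genes rose in 9 and fell in 2 of 13 (KRT8 6.46, the desmosomal DSC2 4.50). These 4 lists had adjusted p = 3.66e-17, 3.02e-12, 0.000124 and 0.00303 with the preset correlation and adjusted p = 0.581 each with an estimated correlation. The class was named from matrix genes such as COL1A1, COL3A1 and DCN, which were not held out of the clustering. The rise of matrix and mesenchymal genes was therefore in part set by how the class was chosen, and is no independent support for its name. BMP and TGF-beta genes rose in 18 and fell in 5 of 29 (TGFBI 6.26, TGFBR3 5.67). This list had adjusted p = 0.00459 with the preset correlation and adjusted p = 0.627 with an estimated correlation. Imprinted genes rose in 11 and fell in 3 of 20 (IGF2R, the receptor that clears IGF2, 3.65, and DLK1 3.44), and trunk HOX genes rose in 7 of 7, none of which reached 50 CPM. For these lists the preset correlation gave adjusted p = 0.0259 and 7.22e-05, and an estimated correlation adjusted p = 0.581 each. IER3 had 5.66 without replicate 1 and 4.12 without replicate 2, and TGFBR3 had 7.81 and 4.46.

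Among lists not called in mesenchyme-like cells, cell cycle genes were higher in 1 and lower in 9 of 35, WNT genes in 10 and 10 of 30, and nutrient transport genes in 7 and 5 of 23. FGF (5 higher, 7 lower of 16), Notch (3, 5 of 16), hedgehog (4, 4 of 11), anterior HOX (4, 2 of 8), pluripotency (5, 5 of 12) and DNA methylation enzymes (2, 5 of 12) were not called either. The rest were interferon response (3, 2 of 9), glycolysis (6, 8 of 23), cholesterol synthesis (7, 1 of 22), steroid synthesis (1, 1 of 5) and hypoxia (5, 5 of 14). Adjusted over the list alone the counts were the same except for imprinted (12 higher), matrix (30 higher), nutrient transport (7 lower), hedgehog (5 higher) and cell cycle (6 lower). Median, mean and test differed in sign for pluripotency, glycolysis, steroid synthesis, WNT, FGF and hedgehog genes. In cells with 10% or more ribosomal protein counts 218 genes were called, 198 of them shared in direction, and HES6 (log2 -4.55) and the imprinted list lost their calls. With the earlier naming rule and the 10-cell minimum together 72 genes were called. Over all 3 classes, camera called 21 of 63 set tests with the preset correlation and 0 with an estimated one, where 2 had an unadjusted p under 0.05. With an estimated correlation camera gave a simulated list of doubled genes an unadjusted p of 0.00927 in the neuron contrast. That was 1 list in 1 draw, so power was not measured. The 0 calls do not by themselves show that no list moved, and the calls depend on the correlation used.

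Trophoblast-like cells, the extraembryonic class, were set against both neural classes. They had high levels of PHLDA2, an imprinted gene that restrains placental growth, which reached 2684 CPM ± 286 against 0.562 ± 0.226 (log2 12.71, SE 0.30). FABP5 reached 2119.6 ± 362 (log2 7.38, SE 0.21, adjusted p = 2.88e-257) and KRT19 1174 ± 347 (5.97, SE 0.21, adjusted p = 1.53e-177). CYP11A1, the enzyme of the first step of steroid synthesis, was 1044-fold higher (95% counting interval 178 to 42141), and RAB25, a GTPase of epithelial recycling, 2543-fold (447 to 101333). AP1M2, an epithelial sorting adaptor, was 681-fold higher (113 to 27791). CRB3, a polarity gene, was at least 136-fold higher, and DKK1, a secreted WNT inhibitor, at least 151-fold. Without replicate 1, RAB25 was 1414-fold, CYP11A1 523-fold, AP1M2 430.4-fold and DKK1 at least 30.7-fold higher. Without replicate 2, PHLDA2 had 13.73, and the bounds were 370.0-fold for RAB25, 163-fold for CYP11A1, 89.7-fold for AP1M2, 95.3-fold for DKK1 and 50.4-fold for CRB3.

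The high genes of trophoblast-like cells were split between its clusters, and several differed between the replicates. All UMIs of PHLDA2, CYP11A1, STAR and PTGS2 in the class lay in cluster 20.0 (18 of 30 cells), and all those of ADM and DKK1 in cluster 25 (12 cells). ADM, a vasodilator peptide (log2 8.77), had 7.09 without replicate 1, and the circadian repressor BHLHE40 (6.53) had 7.21. Without replicates 1 and 2 in turn, FST (6.05, adjusted p = 0.0244) had 3.30 and 7.23, and CLDN3, a tight junction gene (6.10), 4.74 and 7.18. STAR, which brings cholesterol into mitochondria (7.01), had 9.17 and 4.21, and PTGS2, a prostaglandin synthase (6.96), 8.44 and 5.94. The epithelial factor ELF3 had 5.98 in both together. The lowest genes had no UMI in the class, so that each fold is a lower bound. PLAGL1 was at least 30.9-fold lower, the proteoglycan VCAN 14.8-fold, the cationic amino acid transporter SLC7A1 13.6-fold, FSTL1 13-fold and HHIP 12.6-fold. The adaptor GRB10 was at least 9.87-fold lower, SMO 7.80-fold, ZIC5 7.50-fold and CDH3 5.28-fold. From 1 replicate alone these bounds ran from 2.13-fold (CDH3 without replicate 1) to 18.5-fold (PLAGL1 without replicate 2).

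Of the 389 list genes tested, 92 were higher and 113 lower in trophoblast-like cells, and 184 did not pass. The median log2 fold change of all 11470 genes tested was -1.0, or -1.29 with DESeq2's size factors, and 111 of the 113 lower genes lay below the first of these. Epithelial junction genes rose in 17 and fell in 3 of 23 (KRT8 4.76; 4.17 without replicate 1 and 5.43 without replicate 2), and steroid synthesis genes rose in 6 and fell in 1 of 10 (the electron carrier FDX1 2.71, HSD17B12 -1.67). Cell cycle genes rose in 15 and fell in 1 of 35 (the mitotic genes AURKA 3.67 and CDC20 3.06). This rise is against the mean of both neural classes, and neuron-like cells lay below progenitors in 34 of 35 such genes. Trophoblast-like cells were not tested against progenitors alone, so whether they exceeded these is not shown. FGF genes fell in 9 of 16 with none higher (FGF12 at least 4.89-fold and ETV5 at least 6.42-fold lower, or 1.67-fold and 2.58-fold without replicate 1). These 4 lists had adjusted p = 6.79e-09, 0.0107, 0.00153 and 0.0488 with the preset correlation. With an estimated correlation they had adjusted p = 0.128, 0.477, 0.509 and 0.479, and camera called 0 of 21 lists, of which 2 had an unadjusted p under 0.05. In cells with 10% or more ribosomal protein counts 182 genes were called, 164 of them shared in direction, only the epithelial junction and cell cycle lists were called, and ETV5 lost its call.

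Among lists not called in trophoblast-like cells, imprinted genes were higher in 3 and lower in 11 of 21, BMP and TGF-beta genes in 7 and 15 of 28, and WNT genes in 3 and 11 of 29. Hedgehog (0 higher, 7 lower of 11), Notch (0, 4 of 15), pluripotency (0, 5 of 12), DNA methylation enzymes (0, 6 of 12), matrix (2, 7 of 32) and mesenchymal (3, 6 of 17) were not called either. The rest were glycolysis (10, 4 of 23), cholesterol synthesis (7, 2 of 23), nutrient transport (2, 7 of 23), interferon response (3, 2 of 9), anterior HOX (0, 3 of 7), trunk HOX (3, 0 of 7), dissociation stress (5, 4 of 21) and hypoxia (6, 5 of 15). Adjusted over the list alone the counts were the same except for imprinted (12 lower), matrix (6 lower), cholesterol synthesis (6 higher), nutrient transport (6 lower) and Notch (2 lower). For interferon response the median and mean were negative and the test pointed up. No posterior HOX gene had enough counts to be tested in any contrast. The test rested on 16 and 14 cells.

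**Figure D2:**
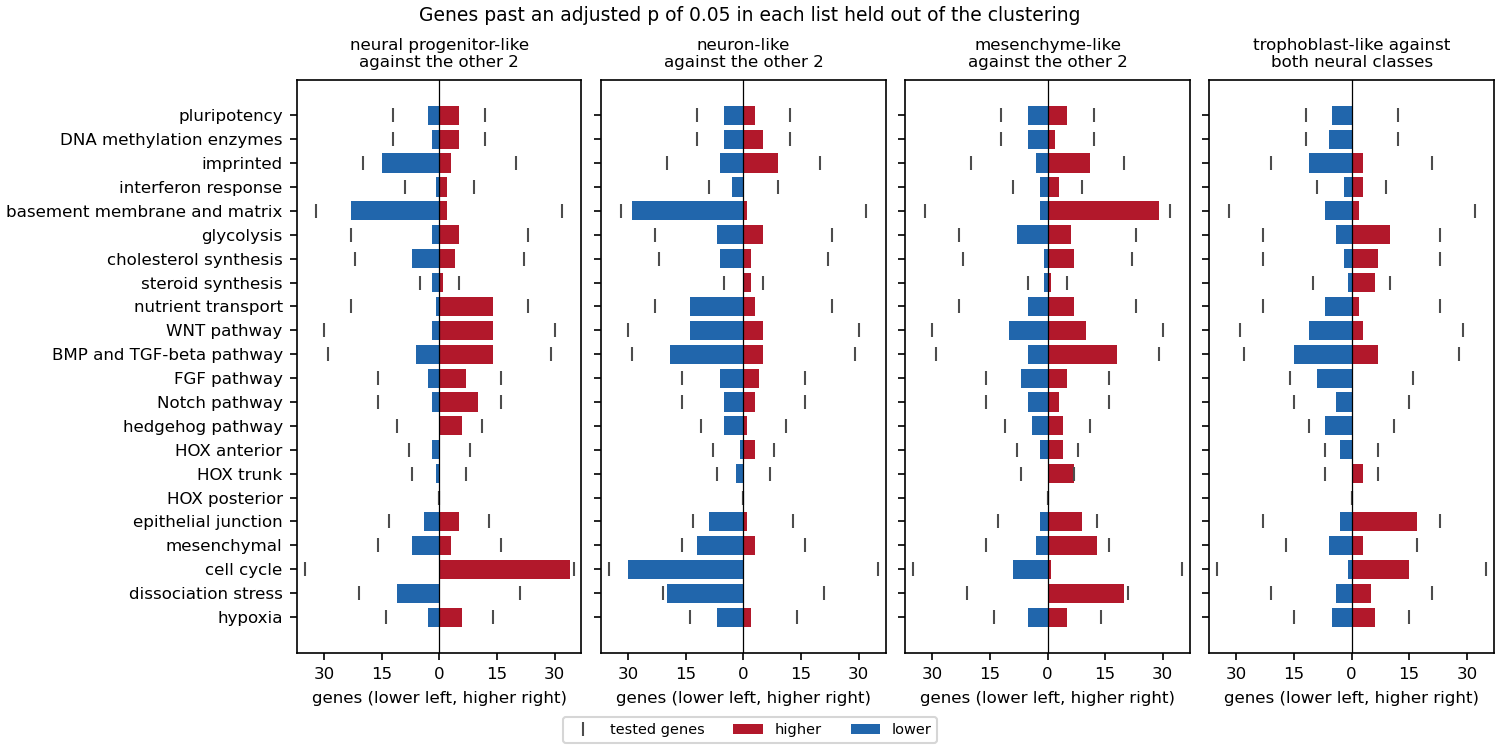
Number of genes past an adjusted p of 0.05 in each of 22 lists held out of the clustering, higher to the right and lower to the left of 0, in 4 contrasts, with vertical marks on both sides at the number of genes tested. In neural progenitor-like cells 34 of 35 cell cycle genes were higher, and in mesenchyme-like cells 29 of 32 matrix genes. Genes correlated with these lists took part in the clustering, so these counts were in part set by how the classes were chosen.

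GFP, a reporter that cattle cells hold only when it has been introduced, has a place in the table of counts and was set out by class after the data were seen. Neural progenitor-like cells held 1362 and 1479 CPM of GFP in replicates 1 and 2, and neuron-like cells 1379 and 1530. Trophoblast-like cells held 44.5 and 22.8 CPM (8 and 3 UMIs) and erythroid-like cells 44.2 and 25.8. Within the mesenchyme-like class cluster 15 held 56.7 and 39.4 CPM (20 and 31 UMIs), whereas cluster 20.2 held 2226 and 371 (254 UMIs in 12 cells and 46 in 14). Over all kept cells the level was 1629 and 1787 CPM. It moved with the ribosomal protein share, with 2762 and 2496 CPM in cells of 10% or more and 671 and 741 in the rest, and in neural progenitor-like cells with 2185 and 2108 against 672 and 677. In the class contrasts GFP did not pass in mesenchyme-like cells (log2 -1.70, SE 0.96, adjusted p = 0.267) or in trophoblast-like cells (log2 -4.64, SE 1.51, adjusted p = 0.0954). Over the alternatives the adjusted p ranged from 1.05e-20 (a minimum of 1000 genes per cell, log2 -4.36) to 0.996 (10 cells per class, -0.12) for mesenchyme-like cells. For trophoblast-like cells it ranged from 6.88e-10 (DESeq2, -5.01) to 0.116 (no filter, -4.81). Neuron-like (log2 1.03, edgeR adjusted p = 0.405) and neural progenitor-like cells (0.67, adjusted p = 0.592) did not pass either. Among the alternatives both passed only at Leiden resolution 0.5 (0.92 and 1.14, edgeR adjusted p = 0.000112 and 1.61e-06) and with 1000 genes per cell (2.63 and 1.73, adjusted p = 7.79e-18 and 1.29e-11).

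**Figure D3:**
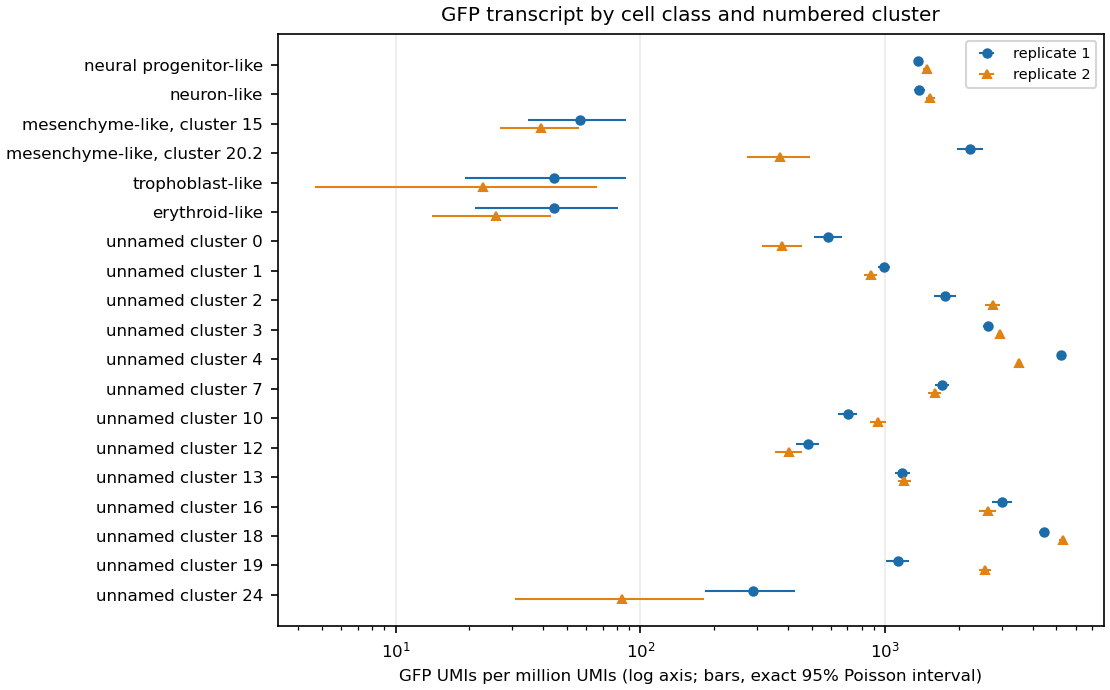
GFP UMIs scaled to CPM by cell class and numbered cluster in replicates 1 (blue circles) and 2 (orange triangles), on a log axis with exact 95% Poisson intervals that cover counting error only. Neural progenitor-like cells held 1362 and 1479 CPM, and mesenchyme-like cluster 15 held 56.7 and 39.4 CPM.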

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

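The tests of GFP, of doublets, of a shared RNA pool, of bare nuclei and of UMIs per cell were chosen after the results were seen, and those of barcode errors and of cytosolic transcripts before.

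GFP had 45680 UMIs in the kept cells and entered no planned comparison, so it stands out as a signal outside the main measurement. Its counts were low in mesenchyme-like cluster 15, trophoblast-like and erythroid-like cells relative to both neural classes. Free RNA as the carrier of the neural counts would keep GFP and HBZ, a globin with a UMI in 82.4% and 82.0% of kept cells, in 1 ratio, but the ratio in neural progenitor-like cells was at least 17.4 times that in cluster 15 and in trophoblast-like cells; erythroid-like cells, which make HBZ, were not tested this way. Fewer UMIs per cell do not account for it, since the median UMIs of progenitors were at most 1.12 times those of the 3 groups, while their GFP UMIs per cell were at least 3.66-fold higher at the limits of the counting intervals. Cell integrity, read from the ribosomal protein share, does not either, since the median share of the 3 groups was at least 3.18 times that of progenitors, in which GFP was at least 3.12-fold higher in cells with 10% or more. A smaller part of donor-derived cells in these classes and a lower activity of the transgene there may each be the source and were not tested, and the design gives no group for a biological explanation.

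In an added fit of the classes together with the numbered clusters, GFP was above the mean of the others in clusters 18 (log2 2.20, edgeR adjusted p = 9.83e-05), 4 (2.17, adjusted p = 3.87e-05) and 3 (1.62, adjusted p = 0.00083). It was below it in clusters 0 (-1.98, adjusted p = 0.00443) and 12 (-1.75, adjusted p = 0.00755) and in mesenchyme-like cells (-1.59, adjusted p = 0.0131), where the value was -3.43 without replicate 1 and -0.63 without replicate 2. Neural progenitor-like (-0.10, adjusted p = 0.913) and neuron-like cells (0.22, adjusted p = 0.695) did not pass. The median ribosomal protein share was 20.7%, 24.2% and 25.0% in clusters 18, 4 and 3, and 2.61% and 2.55% in clusters 0 and 12.

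Clusters 17 and 23, of 63 and 70 cells, lay almost wholly in 1 replicate each and entered no comparison. Doublets do not account for them, since their median UMIs were at most 0.657 times their sample's median. Reading errors of 1 barcode do not either, since 0% of their barcodes lay within 2 bases of another of the cluster. With cells thinned to 1500 UMIs the median index of dispersion of abundant genes was at most 1.12 in both, below the 1.27 to 2.32 of 18 other clusters, so that 1 pool of RNA behind many barcodes may be the source. Why such a pool would arise was not tested, and the design gives no group for a biological explanation.

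Cells with a low ribosomal protein share made up most of both replicates. Few UMIs per cell do not account for them, since 73.3% of the 1048 cells with 5000 to 8000 UMIs had a share under 10%. Bare nuclei stay open, since mean mitochondrial UMIs per cell in these cells were 0.642 to 1.05 times those of the rest over 6 class and replicate pairs, against 0.0885 to 0.144 times for 8 cytosolic transcripts, and free RNA can bring mitochondrial counts. Abundant cytosolic transcripts outside the ribosomal protein genes were lower in these cells, with median log2 ratios from -2.41 to -1.66 over the 6 pairs, consistent with a loss of cytosolic transcripts. Whether this arose in the embryo or during dissociation and sorting was not tested.

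Cluster 24, of 29 cells, was led by WFDC2, ATP6V1G3 and CA12, went unnamed because its leading genes went against its name, and entered no comparison.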

How the results depend on the processing

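The earlier naming rule, the 10-cell minimum, the cells with 10% or more ribosomal protein counts, the pairs of classes and the way values without 1 replicate were fitted were chosen after the results were seen, the other alternatives before. Over RLE size factors, DESeq2, no filter, no replicate block, doublets kept, Leiden resolution 0.5 and 1000 genes per cell, fixed beforehand, the called genes numbered 218 to 277 in neuron-like, 187 to 253 in neural progenitor-like, 216 to 272 in mesenchyme-like and 191 to 213 in trophoblast-like cells. Leiden resolution 2 and scaling within sample were fixed for class shares only. With the earlier naming rule and the 10-cell minimum together they fell to 147, 71 and 72 in the first 3, with the 10-cell minimum alone to 211, 217 and 214, and with the earlier rule to 165 in the trophoblast contrast. The trophoblast contrast could not be run with a minimum of 1000 genes per cell, which left no such class. Without the replicate block the counts were 257, 234, 253 and 206, and of the genes named only KLF2 in neural progenitor-like cells changed its call. Of 133 gene and contrast pairs taken by the naming rule, 133 kept direction and call with RLE size factors, with no filter and with doublets kept, and 131 with DESeq2 and at Leiden resolution 0.5. Of those that could be tested, 22 of 100 lost their call with the 10-cell minimum, 25 of 81 with the earlier rule and that minimum together, 6 of 130 in cells with 10% or more ribosomal protein counts and 2 of 100 with 1000 genes per cell. Without 1 replicate no sign changed in 266 values, of which 66 moved by more than 1.5 times. The naming rule took only genes with 1 sign in both replicates, so the lack of sign changes was mostly set by that selection. Over all genes the naming rule allows, whose narrowing was decided after these values were seen, 3676 values were the same, 245 lost the call, 92 moved and 59 reversed. Those counted as moved are values without 1 replicate, on another scale than the 1.5 times above. For the 133 pairs that scale gave 11 moved without replicate 1 and 25 without replicate 2, against 29 and 37 over 1.5 times.

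Direction turned for FBN1 in neuron-like cells (-0.050) with a minimum of 1000 genes per cell, and for IGF2 in neural progenitor-like cells (0.41) with the 10-cell minimum, which adds classes to the mean. With the earlier rule and that minimum together it turned for ZIC2 in neuron-like (-1.07), LGR5 (-0.20) and KIF11 (-0.049) in neural progenitor-like and ZIC5 (0.19) and HHIP (0.82) in mesenchyme-like cells. The percentage of calls that were higher went from 21.8 to 36.5 in neuron-like and from 66.9 to 84.6 in mesenchyme-like cells with the 10-cell minimum. With the earlier rule and that minimum together it went from 59.1 to 70.4 in neural progenitor-like and from 66.9 to 97.2 in mesenchyme-like cells. Gene lists called by camera went from 21 to 0 with an estimated correlation, and in the cells with 10% or more ribosomal protein counts to 27 with the preset and 0 with an estimated correlation. In the trophoblast contrast they went from 4 to 0 with an estimated correlation, to 2 in those cells and to 0 there with an estimated correlation. Each of these 0 counts came with 2, 2, 2 and 1 lists at an unadjusted p under 0.05. The power of that setting was not measured, since each simulation held 1 doubled list. These 0 counts do not by themselves show that no list moved, and the calls depend on the correlation used.

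The share of neural progenitor-like cells was 12.9% with doublets kept, 18.4% at Leiden resolution 0.5, 1.48% at resolution 2, 14.2% when scaled within sample, 10.6% with 1000 genes per cell and 10.3% with the earlier naming rule. In the same order the unnamed share was 71.6%, 66.3%, 82.1%, 70.4%, 75.6% and 78.4%. Neuron-like cells made up 9.48% with 1000 genes per cell and 6.88% with the earlier naming rule, and mesenchyme-like cells 4.34% at resolution 2 and 1.89% with the earlier naming rule. For all of these the cause was not tested. The trophoblast contrast rested on 16 and 14 cells, and 9 of 42 simulated 2-fold changes were recovered there against 33 of 48 in the neuron contrast; the other contrasts were not simulated.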

Other observations

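All tests of this part were chosen after the result was seen. Clusters without a name also differed in genes held out of the clustering, in the fit that set each class or numbered cluster against the mean of the others. Cluster 0 was high in KLF5, a transcription factor of pluripotent and epithelial cells, at 575 CPM ± 44.9 (SD, n = 2) against 44.0 in the others (log2 4.27, edgeR adjusted p = 2.36e-34). NRARP, a feedback inhibitor of Notch signalling (3.76), and CDK1, the mitotic kinase (3.48), were also high there. Cluster 13 was high in ISG15, a ubiquitin-like protein induced by interferon, at 97.3 CPM ± 29.8 against 5.59 (log2 5.04, SE 0.28, adjusted p = 2.23e-23), together with CDK1 (2.85) and the mitotic motor KIF11 (2.80).

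GLI2, a transcription factor of hedgehog signalling, stood at 114 CPM ± 2.06 in cluster 12 against 10.4 in the others (log2 4.21, adjusted p = 3.84e-24), and HHIP (3.52), the laminin LAMA2 (3.37) and the ligand WNT3 (2.92) were high as well. The co-receptor CDON (2.20) and GLI3 (2.18) were high in cluster 10. In cluster 4, whose leading genes included SHH and FOXA2, the glycolytic enzymes LDHA, at 729 CPM ± 30.4 against 244 (log2 2.21), and PGK1, at 445 CPM ± 9.98 against 142 (2.19, adjusted p = 6.40e-30), were high. The median ribosomal protein share was 24.2% in cluster 4, against 2.61% in cluster 0, 3.23% in cluster 10 and 2.55% in cluster 12, and cytosolic transcripts were lower in cells with a low share. Cluster 7 was high in ENO2 (3.39), DIRAS3 (2.89), the secreted DKK3 (2.70) and HES6 (2.45). Among the list genes set out for cluster 18, PEG3, an imprinted zinc finger gene, stood highest over the others (log2 2.05, adjusted p = 4.12e-24), below GFP (2.20).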
